A study of Mus musculus with 12 samples.

How the data were processed

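RNA sequencing libraries were made from mouse brain perivascular macrophages, the macrophages that lie along the blood vessels of the brain. The series text calls the samples biological replicates of 2 age groups, 18 months (aged, n = 5) and 3 months (young, n = 7). It does not say how many animals or cells each library came from, so p-values measure the spread between these libraries. Per the labels' protocols, cells were lysed in SMART-seq2 buffer, cDNA was primed with oligo-dT and amplified, and libraries were made with the Nextera XT kit and sequenced as DNA nanoballs. This chemistry does not mark the strand and carries no molecular identifiers, so reads of a gene and of an overlapping antisense gene cannot be told apart, and amplified copies count as separate reads. The labels give no sort marker, sex or batch.

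The authors deposited 1 table of 17358 genes. It holds estimated counts per gene, which the authors made with tools that the submitters' processing notes list as HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 on the GRCm38 (mm10) build. The notes give these tools no role or order, and the annotation is not given in the sources used here. Between 88.2% and 90.6% of the deposited estimated counts in a library, zeros included, were whole numbers, and all were rounded before testing. The table also holds normalised values without a named unit. They were read as FPKM deposited by the authors because they scale with the inverse of the library total and of a plausible transcript length (median 2590 bases). Their sums ranged from 720216 to 884648 per library. The FPKM values were used in 1 alternative and to obtain transcript lengths. The authors' group means equalled the means of the library columns to within 4e-06 and were not used further. No column of another sample was present.

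Library totals ranged from 23214816 to 30628789 counts. A floor of 3 counts corresponded to between 0.098 and 0.129 CPM, counts scaled by the library total,, and floors and counting intervals (95%, Clopper-Pearson) cover counting error only. No pair of libraries agreed within sampling noise (chi-square per degree of freedom from 281.9 to 809.6 over all pairs), so none was treated as a repeat deposit. Gene symbols damaged or repeated in the table (32) were replaced through their Entrez identifiers with a RefSeq gene table of GRCm38.p6. It matched 17244 of the 17358 identifiers and gave the coordinates, which are 1-based. Estimated counts share reads between near-identical genes, so levels of paralogs such as the globins, the Cd209 and Ms4a families and the MHC genes are uncertain. The same holds for Plin2, which shares its locus with a transcribed pseudogene.

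Aged and young libraries were compared gene by gene with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test used TMM factors, the filterByExpr filter on group and robust estimation of the spread. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and positive log2 fold changes are higher in aged libraries. The edgeR estimation mode was not fixed beforehand: the installed version's default (legacy estimation) was fitted first and kept, and the bias-adjusted mode (legacy=FALSE) was fitted afterwards. It called 38 genes in place of 1, and its calls are given as an alternative. Other alternatives, planned and added, were also fitted before the final tables were made, and none replaced the first fit. Levels are TMM-normalised CPM as mean ± SD. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. DESeq2 1.42.0 and limma 3.58.1 with voom were alternatives. On simulated counts for the 9550 tested genes, with 200 genes changed, the test called 0% of the 2-fold, 72% of the 4-fold, 64% of the 8-fold and 92% of the 16-fold changes among genes of at least 50 CPM. Among genes under 50 CPM it called 0%, 0%, 0% and 12%. In all it called 63 genes, 3 of them unchanged ones. The simulated 2-fold and 4-fold changes were all increases in aged libraries, and the 8-fold and 16-fold ones all decreases. Size and direction were therefore not separated, and the recovery of 2-fold and 4-fold decreases is not known. The main fit called fewer genes than the simulation, which makes its adjusted threshold harder to pass. The simulated rates may therefore overstate the recovery in the real comparison.

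Gene lists for 16 cell types and 25 pathways were fixed before the data were examined. They were tested with camera of limma at a preset inter-gene correlation of 0.01, and p-values were adjusted over the 36 lists with at least 3 tested genes. The camera test with an estimated correlation and the self-contained rotation test fry were alternatives. Markers were also averaged per library as the mean of log2(CPM + 1), without scaling factors, and compared by an exact two-sided permutation test over the splits of the 12 libraries into 5 and 7. The numbers of detected genes and library totals were compared by the same exact test.

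The genes named were set by a rule written before the data were examined. Of the genes past the threshold with a mean of at least 10 CPM in the higher group, a regular symbol and a constant sign over every left-out library, the 12 with the smallest p per direction were named. As fewer passed, the 4 with the smallest unadjusted p per direction were added and are said not to have passed. From each list up to 4 members past the threshold were named, or the 2 with the smallest p as values. Mrc1, Cd163, Lyve1, Pf4, F13a1, Cd74, H2-Ab1, Apoe, P2ry12 and Tmem119 were always named. Any other gene named was chosen after its values were seen. Results of some single genes that the rule or the lists would name are not reported here.

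Alternatives fixed beforehand were other scaling factors, no filter, a filter of 10 CPM in 5 libraries, DESeq2, limma-voom with quality weights, a spread that was not robust, the replicate number as a block, the number of detected genes or 1 surrogate variable (sva 3.50.0) as a covariate, other thresholds, and each library left out in turn. Chosen after the data were seen were legacy=FALSE, limma on log2(FPKM + 1) for genes of at least 1 FPKM in 5 libraries, an offset for transcript length, and a fit without aged libraries 1, 3 and 4. The choroid plexus list without Ttr was also added then. Other pseudocounts, which had been planned for normalised values, were not needed because counts were tested. Exact tests and tables were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.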

Results

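The transcriptome of mouse brain perivascular macrophages was profiled by SMART-seq2, a full-length cDNA method for small amounts of RNA, in 5 libraries from aged mice (18 months) and 7 from young adults (3 months). Library totals ranged from 23214816 to 30628789 estimated counts, with 26222244 ± 2872552 (SD, n = 5) in aged and 28766060 ± 1751585 (SD, n = 7) in young libraries (exact two-sided permutation p = 0.096). The number of genes with a count above 0 was 10775 ± 269 in aged and 10708 ± 490 in young libraries (exact two-sided permutation p = 0.79), and the number with at least 5 counts was 8660 ± 733 against 9210 ± 868 (exact two-sided permutation p = 0.255). The spread between libraries was wide, with a common biological coefficient of variation of 1.33.

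The design asks how gene expression of these macrophages differs between aged and young adult brain. Ttr, which encodes the thyroxine carrier transthyretin and is known for its high expression in choroid plexus epithelium, rose 6.39-fold in aged libraries, from 93.0 ± 34.8 to 595 ± 376 normalised CPM (SD, n = 7 and n = 5). All 5 aged libraries lay above all 7 young ones. Its log2 fold change was 2.68 ± 0.39 (SE), with an adjusted p of 0.0297 by the edgeR quasi-likelihood test. Ttr (Entrez 22139) lies on chromosome 18 from 20664209 to 20674326 of GRCm38. It was the only gene past the threshold among the 9550 tested, and no gene was lower. At an unadjusted p under 0.05 there were 570 genes, 368 higher and 202 lower in aged libraries. The groups did not overlap for 57 genes (31 higher and 26 lower), against 24.1 by chance (0.25% of genes). The 24.1 is only the mean expected over all splits. Genes vary together across libraries, and the excess over that mean was not tested.

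Both the size of the response and the call of Ttr depended on the estimation and on single libraries. DESeq2 called 64 higher and 57 lower genes, edgeR with legacy=FALSE (chosen after the data were seen) 36 higher and 2 lower, and the edgeR fit without aged library 2 called 61 higher and 14 lower. Ttr was not called (adjusted p between 0.0526 and 0.16) on leaving out aged library 1 or 4 or young library 1, 2, 3, 4, 5 or 7. Its call was also lost with voom weights (0.086), with the replicate number as a block (0.683) and without aged libraries 1, 3 and 4 (0.766). The log2 fold change of Ttr stayed between 2.36 and 2.88 over the single libraries left out.

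The 4 genes added by the naming rule that were higher in aged libraries did not pass. Ccl8, which encodes a chemokine that attracts monocytes and other leukocytes, was at 4094 ± 2110 normalised CPM in aged and 801 ± 560 in young libraries (log2 fold change 2.35 ± 0.40, adjusted p = 0.062 by edgeR's quasi-likelihood test). Its groups did not overlap. Sephs2, a selenophosphate synthetase, was at 311 ± 187 against 75.6 ± 12.9 normalised CPM (log2 fold change 2.04, adjusted p = 0.062), also without overlap. Skil, a repressor of TGF-beta signalling, was at 2013 ± 1335 against 529 ± 119 normalised CPM (adjusted p = 0.080). Clasp2, a microtubule-associated protein, was at 906 ± 436 against 333 ± 50.6 (adjusted p = 0.11). Without aged library 2 all 4 passed (adjusted p of Ccl8 0.0149, Sephs2 0.0059, Skil 0.0039 and Clasp2 0.0059), as did Sephs2 without aged library 5 (adjusted p = 0.0211) and Ccl8 without young library 1 (adjusted p = 0.0079). All 4 were also called by DESeq2 (adjusted p from 6.6e-05 to 0.0039) and by edgeR with legacy=FALSE (adjusted p from 4.2e-05 to 0.0064). Ccl8 passed with the transcript length offset too (adjusted p = 0.0336). Without aged libraries 1, 3 and 4, which stood apart on the first principal component, the log2 fold change of Sephs2 was 0.82, of Skil 0.88 in place of 1.93, of Clasp2 0.48 in place of 1.44 and of Ccl8 2.11. Ccl8 lies on chromosome 11 from 82115185 to 82116799 and Sephs2 on chromosome 7 from 127271879 to 127274059.

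The 4 added genes that were lower in aged libraries did not pass either. Mobp, which encodes a myelin protein of oligodendrocytes, had 5 counts over all aged libraries and 3160 over all young ones. Allowing for library totals its level was 412 times higher in young libraries (95% counting interval 176 to 1268). Young libraries held between 76 and 1176 counts, and the adjusted p was 0.177. Junb, an immediate-early transcription factor, was at 189 ± 70.6 normalised CPM in aged and 415 ± 97.5 in young libraries (adjusted p = 0.187). Pttg1ip was at 40.6 ± 27.5 against 140 ± 41.0 and Tmem128, which encodes a transmembrane protein, at 37.0 ± 8.0 against 98.9 ± 20.2 normalised CPM (adjusted p = 0.197 for both). Pttg1ip passed without aged library 2 (adjusted p = 0.0146). DESeq2 called all 4 as lower (adjusted p of Mobp 1.2e-09, Tmem128 5.6e-04, Junb 0.0039 and Pttg1ip 0.0048), whereas edgeR with legacy=FALSE called none of them.

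**Figure D1:**
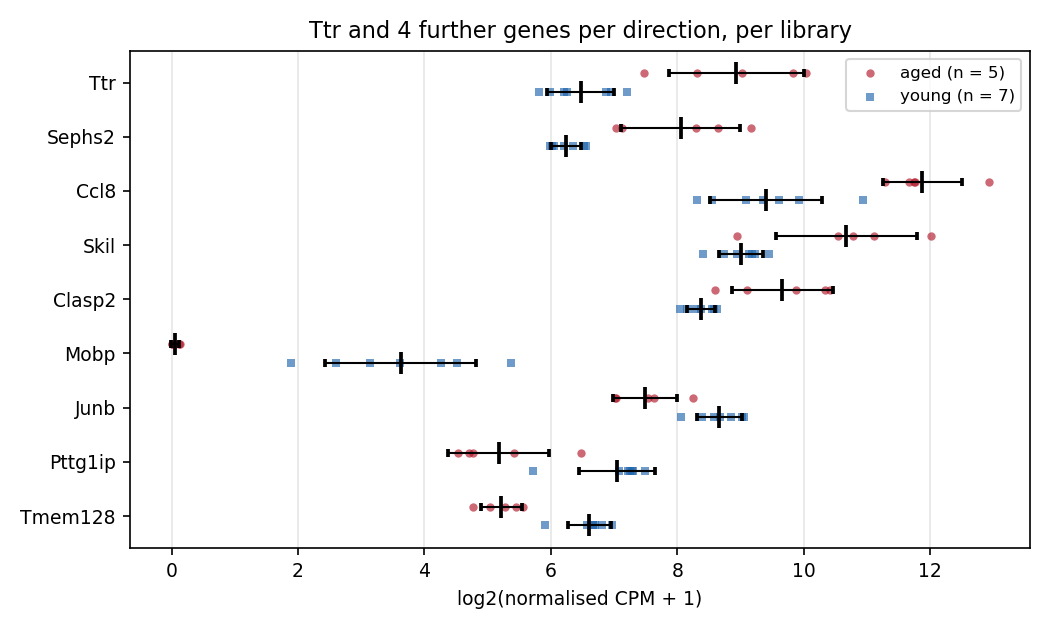
Levels of Ttr and of 8 genes that did not pass, 4 per direction taken by the naming rule, as log2(normalised CPM + 1), in 5 aged (circles) and 7 young (squares) libraries, with the mean (vertical bar) and SD (horizontal bar). Only Ttr passed the test; all aged libraries lie above all young ones for Ttr, Sephs2 and Ccl8, and below them for Mobp and Tmem128.

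Of the 36 gene lists with enough tested members, camera with its preset correlation called 2, the choroid plexus and ependyma markers as higher and the lysosome genes as lower in aged libraries. Neither was called with an estimated correlation (adjusted p = 0.205 and adjusted p = 0.621). The choroid list rested on 3 tested genes, all with positive log2 fold changes (median 2.71, camera adjusted p = 0.00154, and adjusted p = 0.205 with an estimated correlation). One of them, Ttr, passed over all genes tested, and Ttr and Kcnj13 passed adjusted over the list alone. Kcnj13, a potassium channel of transporting epithelia, was at 40.8 ± 26.6 normalised CPM in aged and 0.375 ± 0.992 in young libraries, and Prlr, the prolactin receptor, at 2.66 ± 5.01 against 0.402. Kcnj13 had 84 counts in young library 4 and 0 in the other young libraries, and only 1 count in aged library 5. The log2 fold change of Prlr, 2.71, rested on aged library 2 (344 counts, at most 18 in the other aged libraries) and was 0.09 without it, where the camera adjusted p of the list was 0.0465. For the choroid list fry gave an adjusted p of 0.0166, and without Ttr the camera adjusted p was 0.102. On leaving out young library 4 or 5 the list had fewer than 3 tested genes and gave no value.

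In the lysosome list 26 of 29 tested genes had negative log2 fold changes (median −0.29, camera adjusted p = 0.00838, and adjusted p = 0.621 with an estimated correlation). With all 12 libraries none passed on its own, whether over all genes tested or adjusted over the list alone. Ctsd, the protease cathepsin D, was at 623 ± 323 normalised CPM in aged and 1181 ± 426 in young libraries. Hexa, a subunit of beta-hexosaminidase, was at 550 ± 299 against 914 ± 182. The list was not called by fry (adjusted p = 0.141), or without aged library 3 (0.0935) or aged library 4 (0.0653). Without aged library 2 its camera adjusted p was 8.4e-04, and Ctsa, Ctsb, Hexa and Ctsz passed as lower over all genes tested (edgeR adjusted p from 0.0213 to 0.033); Ctsa, Ctsb and Ctsz are named after their values were seen. Aged libraries 1, 3 and 4 stood apart from the other libraries on the first principal component, and without all 3 of them the adjusted p of the lysosome list was 0.701.

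Genes that mark perivascular macrophages were not called as a group. None of the 24 tested members passed over all genes or adjusted over the list alone (median log2 fold change 0.08, camera adjusted p = 0.795). Cd163, the haemoglobin scavenger receptor, was at 477 ± 64.2 normalised CPM in aged and 310 ± 72.2 in young libraries (adjusted p = 0.448), and Apoe at 16758 ± 9142 against 25703 ± 5229 (log2 fold change −0.62). Apoe passed as lower without aged library 2 (log2 fold change −1.0, adjusted p = 0.0293), but its log2 fold change was −0.14 with a transcript length offset and −0.14 without aged libraries 1, 3 and 4. The mannose receptor Mrc1 was at 2575 ± 342 against 2229 ± 444, Lyve1 at 384 ± 141 against 337 ± 156, Pf4 at 4135 ± 1214 against 5375 ± 1711 and F13a1 at 878 ± 263 against 709 ± 177. The sign of Lyve1 turned with 1 surrogate variable and without aged libraries 1, 3 and 4, and that of Pf4 with a transcript length offset.

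Of the 16 microglia markers, 13 had negative log2 fold changes (median −0.50), with a camera adjusted p of 0.129 and none past the threshold. P2ry12 was at 746 ± 323 normalised CPM in aged and 1014 ± 332 in young libraries and Tmem119 at 2.41 ± 2.93 against 25.5 ± 24.1 (adjusted p = 0.847), and Fcrls at 743 ± 439 against 1137 ± 255, whereas Siglech was at 570 ± 94.2 against 403 ± 82.1. Fcrls, with a log2 fold change of −0.61, passed as lower without aged library 2 (log2 fold change −1.05, adjusted p = 0.027), and its log2 fold change was −0.12 without aged libraries 1, 3 and 4.

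Antigen presentation and interferon genes gave no call by camera. The MHC class II list had 6 positive and 5 negative members (median 0.05, adjusted p = 0.86); its members H2-DMa and H2-DMb1 were at 490 ± 174 against 346 ± 140 and 277 ± 172 against 204 ± 60.1 normalised CPM, aged against young. Cd74, the invariant chain, was at 6412 ± 3018 against 6673 ± 2204 and H2-Ab1 at 1147 ± 794 against 1329 ± 435. The signs of both turned under some alternatives, among them the transcript length offset and the fit without aged library 4. The MHC class I list was divided 8 to 8 (adjusted p = 0.805), with H2-T23 at 672 ± 186 against 466 ± 90.7 and the immunoproteasome subunit Psmb8 at 324 ± 129 against 430 ± 126. In the type I interferon list, 15 of 29 members were positive (adjusted p = 0.912); Ifi27l2a was at 854 ± 301 against 506 ± 74.1 and Ifi204 at 421 ± 105 against 257 ± 46.3.

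Among 20 tested chemokines and receptors, 12 were positive (median 0.17, camera adjusted p = 0.36), and Ccl8 alone passed adjusted over the list alone. Ccl2, a monocyte chemoattractant, was at 5063 ± 1847 normalised CPM in aged and 2770 ± 1100 in young libraries. The NF-kB list had 14 positive members of 23 (median 0.30, adjusted p = 0.402), with Nfkbiz at 1049 ± 486 against 469 ± 202 (adjusted p = 0.0229 without aged library 2). The log2 fold change of Nfkbiz was 1.16, and 0.57 without aged libraries 1, 3 and 4. The immediate-early and dissociation list had 15 positive members of 22 (median 0.38, adjusted p = 0.129). Adjusted over the list alone, its members Klf2, at 1231 ± 307 against 738 ± 150 normalised CPM, and Junb passed, in opposite directions. Of 11 complement genes 4 were positive (median −0.44, adjusted p = 0.795). C4b (190 ± 51.8 against 97.7 ± 36.5 normalised CPM) was higher and C5ar1 (379 ± 90.5 against 609 ± 174) and C1qa lower adjusted over the list alone, though not over all genes tested.

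The fry test of a change in either direction gave adjusted p-values of 0.00148 for chemokines, complement and antioxidant genes, 0.0142 for immediate-early genes, 0.034 for oligodendrocyte markers and 0.0432 for interferon genes and disease-associated genes. This test asks only whether members of a list differ between the groups, and not whether they differ more than other genes.

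Of the disease-associated and lipid-associated macrophage genes, 13 of 17 were negative (median −0.47, camera adjusted p = 0.129); the tetraspanin Cd9 was at 44.9 ± 37.6 against 143 ± 74.5 normalised CPM. The cholesterol and lipid list had 11 positive members of 19 (median 0.16, adjusted p = 0.129). Insig1, a sterol-sensing regulator of cholesterol synthesis, was at 1017 ± 639 against 252 ± 107 and passed adjusted over the list alone but not over all genes tested (adjusted p = 0.139, and 0.0059 without aged library 2). Soat1 was at 129 ± 19.9 against 67.3 ± 31.9. Scavenger and efferocytosis receptors had 14 positive members of 23 (adjusted p = 0.912), with the fatty acid receptor Cd36 at 449 ± 110 against 733 ± 201. Autophagy genes were divided 9 to 10 (adjusted p = 0.805), with Atg3 at 125 ± 28.2 against 78.4 ± 16.7 and Tbk1 at 97.1 ± 46.8 against 51.0 ± 16.8. Iron-handling genes had 6 positive members of 14 (adjusted p = 0.795), with Blvrb at 353 ± 162 against 537 ± 123.

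The NADPH oxidase and nitric oxide list had 5 negative members of 6 (median −0.64, camera adjusted p = 0.142). Rac2 was at 38.6 ± 29.0 against 106 ± 25.8 normalised CPM and passed adjusted over the list alone, and the oxidase subunit Cyba was at 336 ± 146 against 589 ± 218. Antioxidant genes had 8 negative members of 13 (adjusted p = 0.804), with Gpx4 at 204 ± 92.0 against 361 ± 92.3 and Txnrd1 at 11.7 ± 11.7 against 0.32 ± 0.57. Of 50 nuclear-encoded oxidative phosphorylation genes 27 were positive (median 0.07, adjusted p = 0.402). The complex I subunit Ndufv1 was at 2.48 ± 2.58 against 38.9 ± 23.7 and Cox7c at 505 ± 223 against 290 ± 76.1. Glycolysis genes had 7 positive members of 16 (adjusted p = 0.795), with Ldha at 66.6 ± 68.0 against 184 ± 38.3 and Gpi1 at 96.0 ± 31.2 against 54.3 ± 19.1. Cytoplasmic ribosomal protein genes had 30 positive members of 55 (median 0.05, adjusted p = 0.77), with Rps7 at 642 ± 244 against 400.2 ± 64.6 (adjusted p = 0.0489 without aged library 2) and Rps14 at 2082 ± 574 against 1465 ± 212. Without aged libraries 1, 3 and 4 the log2 fold change of Rps7 was 0.25 in place of 0.68. None of the 26 mitochondrially encoded names of the list was analysed here.

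Unfolded protein response genes had 11 positive members of 19 (median 0.12, adjusted p = 0.402). Dnajb9, a chaperone of the endoplasmic reticulum, was at 577 ± 397 against 222 ± 68.8 normalised CPM and passed adjusted over the list alone (adjusted p over all genes tested 0.0461 without aged library 2), and Canx was at 1554 ± 382 against 1094 ± 155. The log2 fold change of Dnajb9 was 0.26 without aged libraries 1, 3 and 4 in place of 1.38. Cell cycle genes were divided 4 to 4 (adjusted p = 0.86), with Birc5 at 0.269 ± 0.174 against 6.29 ± 15.5 and Pcna at 147 ± 91.9 against 103 ± 34.5. The young mean of Birc5 rested on young library 2 (41.4, the others at most 0.84), and without it the log2 fold change was −0.71 in place of −4.53. That of Pcna was 0.09 without aged library 3 in place of 0.51. Senescence-associated genes had 4 positive members of 7 (adjusted p = 0.795), with Trp53 at 23.9 ± 21.97 against 50.5 ± 30.3 and Gdf15 at 2.41 ± 4.98 against 8.22 ± 10.2 (log2 fold change −1.77, −5.44 without aged library 2 and −0.96 without young library 1). Matrix remodelling genes had 7 positive members of 11 (median 0.19, adjusted p = 0.385), with Itga6 at 68.2 ± 30.2 against 43.7 ± 23.1 and Mmp14 at 4.93 ± 4.16 against 1.10 ± 1.87. Vascular growth factors and receptors also had 7 positive of 11 (median 0.15, adjusted p = 0.795), with Tgfbr2 at 305 ± 66.6 against 243 ± 61.9 and Hgf at 1.08 ± 2.41 against 8.94 ± 8.66. Only aged library 5 held Hgf among aged libraries (5.39), and without it the log2 fold change was −10.96 in place of −3.04. The aged libraries left were then all at 0, so the size of −10.96 carries no meaning.

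Circadian clock genes had 6 positive members of 10 (median 0.18, adjusted p = 0.795). Nr1d1, a repressor of the clock, had 1 count over all aged and 1061 over all young libraries, a ratio of 691 with a counting interval of 124 to 27312, although at least 1 young library had 0 counts. It passed adjusted over the list alone, as did Bhlhe41 in the other direction (662 ± 259 against 382 ± 83.2 normalised CPM), but neither passed over all genes tested. Median, mean and camera direction did not share 1 sign for the fibroblast, MHC class I, interferon, scavenger, autophagy, antioxidant, oxidative phosphorylation, senescence, vascular and circadian lists.

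**Figure D2:**
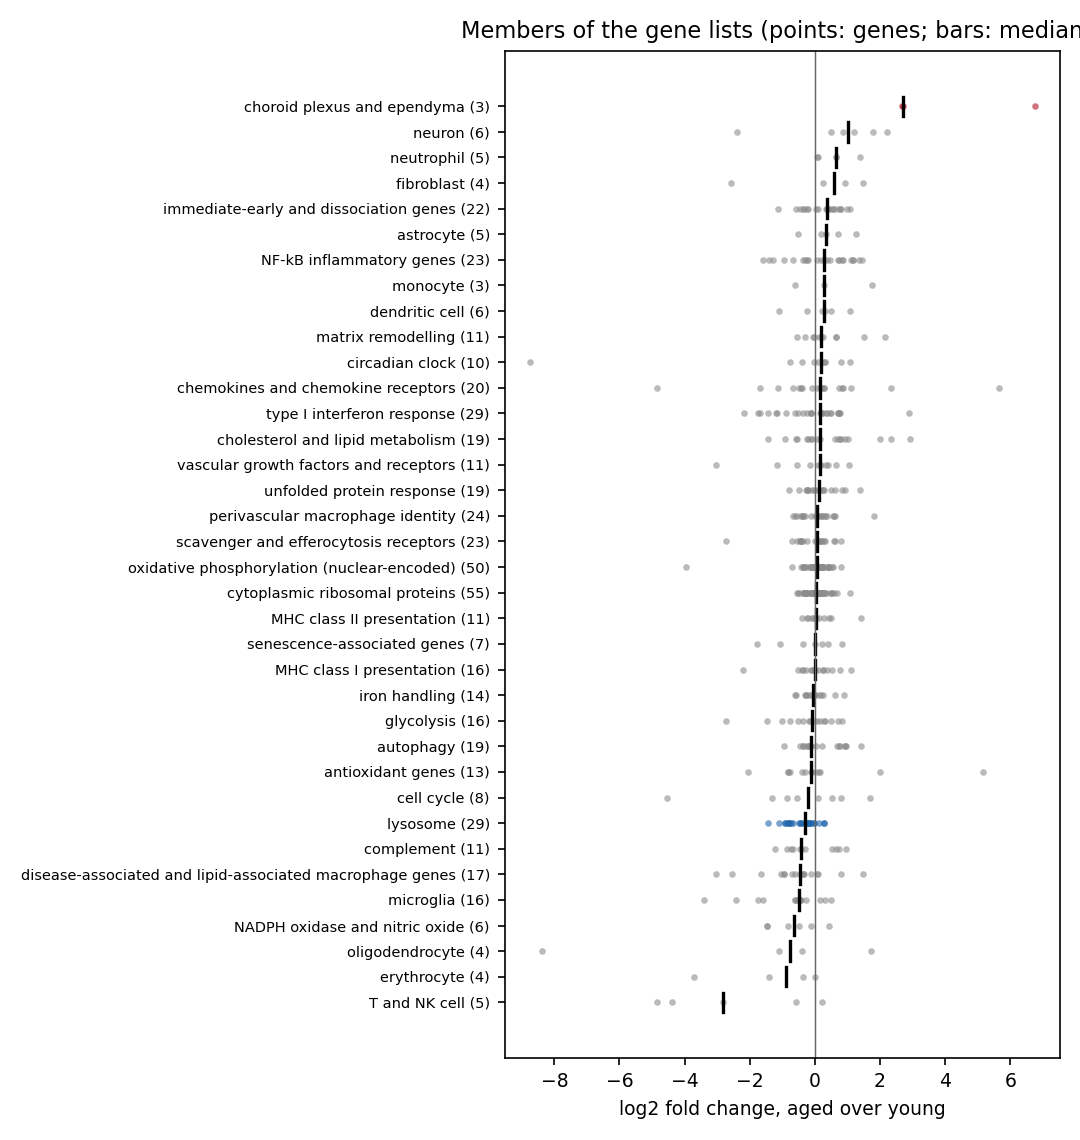
Log2 fold changes (aged over young) of the tested members of the 36 lists, with 1 point per gene, the median as a black bar and the number of tested genes in brackets. The choroid plexus list (red, median 2.71) and the lysosome list (blue, median −0.29) were called by camera at its preset correlation, though not with an estimated one (adjusted p = 0.205 and adjusted p = 0.621); grey lists were not called.

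Markers of cell types other than macrophages were compared per library as the mean log2(CPM + 1) of each list. The choroid plexus and ependyma level was 2.27 ± 0.67 in aged and 1.02 ± 0.18 in young libraries (exact two-sided permutation p = 0.00253, the smallest that splits of 5 and 7 libraries can give; adjusted p = 0.0404 over 16 lists), and was higher in all 5 aged libraries than in any young one. The T and NK cell level was 0.88 ± 0.33 in young and 0.43 ± 0.11 in aged libraries (exact permutation p = 0.00505, adjusted p = 0.0404). Both levels lay near the floor, with medians over the list of 0.14 in young and 0.07 in aged libraries. Cd3e was at 0.232 CPM in young and 0.067 in aged libraries, so a lower number of such cells cannot be read from this list. Among the 5 tested genes of the list Ccl5 was at 0.306 ± 0.189 normalised CPM in aged and 8.86 ± 8.89 in young libraries and Nkg7 at 0.286 ± 0.267 against 6.05 ± 11.3, and the list was not called by camera (adjusted p = 0.556). With the median over each list in place of the mean, neither difference passed.

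The microglia level was 5.83 ± 0.80 in aged and 6.74 ± 0.43 in young libraries (exact permutation p = 0.048, adjusted p = 0.256), and the macrophage level 8.93 ± 0.18 against 8.96 ± 0.20. Neutrophil markers were at 1.91 ± 0.76 against 1.41 ± 0.49, with Cxcr2 at 68.3 ± 41.2 against 43.7 ± 13.4 and S100a8 at 8.54 ± 6.88 against 3.25 ± 3.59 normalised CPM. Monocyte markers were at 1.43 ± 0.36 against 1.4 ± 0.45. Of these Ms4a4c, at 229 ± 97.8 against 68.2 ± 38.1 normalised CPM, passed adjusted over the list alone (adjusted p = 0.197 over all genes), and Itga4 was at 26.7 ± 21.7 against 40.9 ± 32.2 (log2 fold change −0.62, and −0.19 without young library 7). Dendritic cell markers were at 2.53 ± 0.29 against 2.46 ± 0.52, with Cd209a at 1947 ± 490 against 916 ± 756 and Naaa at 10.8 ± 7.86 against 23.2 ± 12.9 normalised CPM. Camera gave adjusted p-values of 0.207 for neutrophil, 0.402 for monocyte and 0.795 for dendritic cell markers.

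Astrocyte markers were at 1.63 ± 0.43 against 1.28 ± 0.45 in aged and young libraries (camera adjusted p = 0.44), with S100b at 11.5 ± 9.26 against 4.77 ± 6.72 and Slc1a2 at 9.94 ± 6.99 against 6.02 ± 9.81 normalised CPM. Neuron markers were at 1.32 ± 0.42 against 1.0 ± 0.62 (camera adjusted p = 0.129), with Rbfox3 at 0.689 ± 0.911 against 3.61 ± 4.11 and Slc17a7 at 4.80 ± 4.39 against 1.03 ± 1.66. Oligodendrocyte markers were at 1.17 ± 0.35 against 1.44 ± 0.34 (camera adjusted p = 0.251), and Mobp passed adjusted over the list alone. The fry test called this list lower in aged libraries (adjusted p = 6.0e-04), a list of 4 tested genes that includes Mobp.

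Fibroblast markers were at 1.04 ± 0.76 against 0.91 ± 0.61 (camera adjusted p = 0.86), with Slc6a13 at 0.266 ± 0.496 against 1.6 ± 2.86 and Ogn at 11.1 ± 21.9 against 3.95 ± 7.56 normalised CPM (log2 fold change 1.49, and −1.57 without aged library 5). Erythrocyte markers were at 1.10 ± 0.76 against 1.32 ± 0.95 (camera adjusted p = 0.86), with Hbb-bt at 0.308 ± 0.584 against 4.09 ± 5.06 and Hba-a1 at 8.48 ± 10.4 against 22.5 ± 47.2 (log2 fold change −1.41, and 0.85 without young library 7). Endothelial (0.28 ± 0.28 against 0.20 ± 0.20), mural (0.32 ± 0.24 against 0.47 ± 0.28), B cell (0.38 ± 0.21 against 0.50 ± 0.18) and sex-linked markers (0.19 ± 0.39 against 0.22 ± 0.37) were near the floor, and these lists had fewer than 3 tested genes. The B cell gene Cd79b was at 10.6 ± 12.5 against 24.7 ± 30.3 (log2 fold change −1.22, and −0.39 without young library 6) and the glucose transporter gene Slc2a1 at 3.36 ± 5.47 against 3.73 ± 6.41 normalised CPM (log2 fold change −0.15, and 0.07, 0.17 and 0.14 without aged library 1, 2 and 4).

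**Figure D3:**
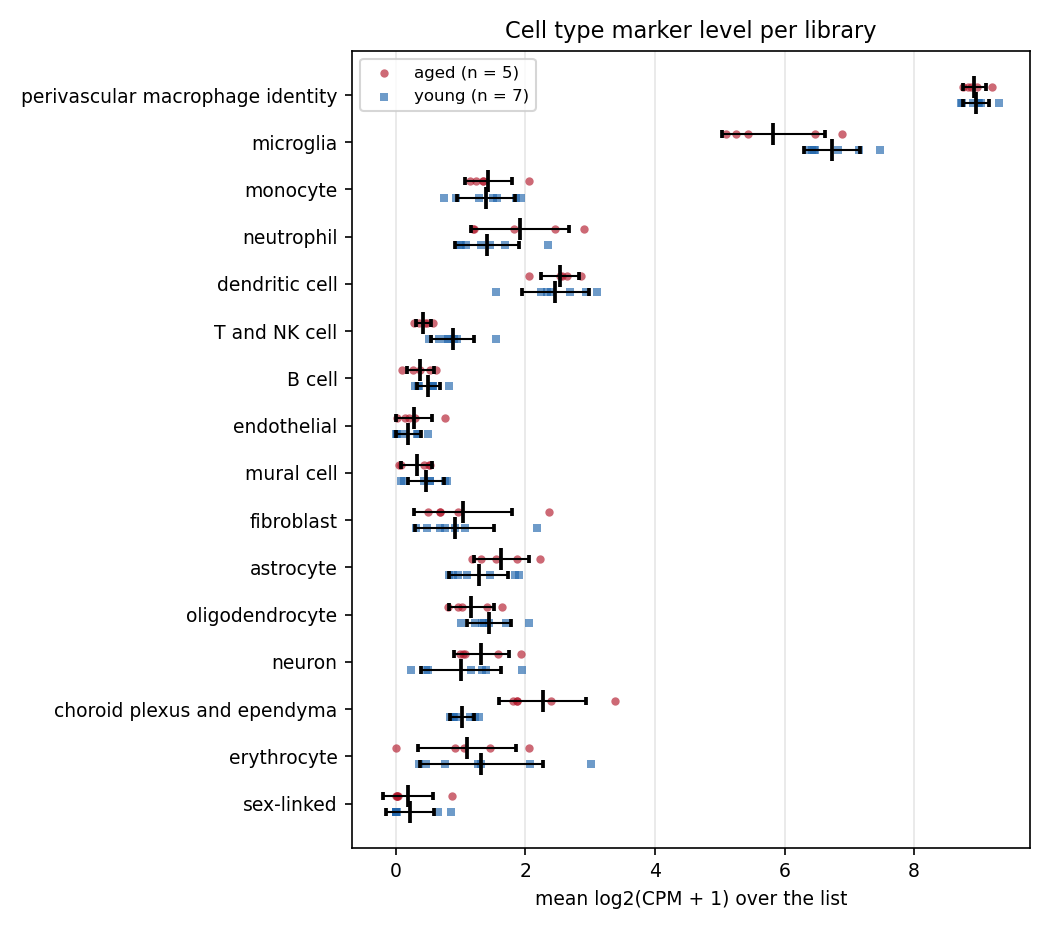
Mean log2(CPM + 1) of the marker genes of 16 lists in 5 aged (circles) and 7 young (squares) libraries, with the mean (vertical bar) and SD (horizontal bar). Macrophage markers lie near 9 in both groups, and the choroid plexus and ependyma level is higher in every aged library (group means 2.27 and 1.02).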

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

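Values were compared within each age group by the gap between the highest or lowest library and its neighbour, divided by the range. Of 80 such groups of 5 or 7 libraries, 10 held a library past the 95% limit. About 1 in 20, or 4, would pass it if values were normal and groups independent. Gene levels were not put on a log scale and the groups share libraries, so 4 is only a rough guide. All of the values below are of this kind, and no explanation was tested for them.

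Aged library 1 had the highest Ccl8 level, 7803 normalised CPM, with the other aged libraries between 2501 and 3472. Young library 1 had 1962 normalised CPM of Ccl8, with the other young libraries between 317 and 977, so the lowest aged library still lay above it. Apoe was at 32526 normalised CPM in aged library 2, with the other aged libraries between 10498 and 16296. Pttg1ip was at 51.6 normalised CPM in young library 6, against 134 to 179 in the other young libraries.

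The 10 most abundant genes took 14.6% of the counts in aged library 5, against 18.3% to 19.5% in the other aged libraries. This library also had the highest mean marker level, as log2(CPM + 1), of monocytes (2.06, others up to 1.35) and of fibroblasts (2.36, others up to 0.96) among aged libraries. Young library 7 had the highest level of T and NK cell markers (1.55, others up to 0.95) and of fibroblast markers (2.17, others up to 1.06) among young ones. The sex-linked list was at 0.88 in aged library 4 and at most 0.03 in the other aged libraries. In young libraries 2 and 3 it was at 0.85 and 0.65, so the level is not particular to aged library 4. The 4 genes of this list that could be read, Eif2s3y, Ddx3y, Uty and Kdm5d, are all Y-linked. Eif2s3y reached 9.57 CPM, whereas Ddx3y reached at most 0.125, Uty 0.037 and Kdm5d 0.033 CPM in any library. The level therefore rested on Eif2s3y and does not give the sex of a library.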

How the results depend on the processing

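The legacy=FALSE, FPKM and length settings and the omission of Ttr or of aged libraries 1, 3 and 4 were chosen after the data were seen; the cause of each difference was not tested except where stated. The count of genes called was 1 in the main fit, with DESeq2 size factors, without robust spread and with the 2-fold limit. It was 3 with library totals, 4 with upper-quartile factors, 13 without a filter, 4 with at least 10 CPM in 5 libraries, 121 with DESeq2 (64 higher, 57 lower; 37 of the lower had a mean under 10 CPM, and 234 genes had no adjusted p) and 3 with voom weights. It was 2 with detected genes as a covariate, 3 with 1 surrogate variable, 5 at an adjusted p under 0.1, 38 with legacy=FALSE, 6 on FPKM, 2 with the length offset and 0 without aged libraries 1, 3 and 4, a fit of fewer libraries. Leaving out 1 library gave 0 to 75 genes: 75 without aged library 2, 3 without aged library 5, 2 without young library 1, 1 without aged library 3 or young library 6, and 0 without any other. The sets from DESeq2 and legacy=FALSE shared 33 genes, and 26 of these were also called without aged library 2. Ttr kept its sign under every alternative run (log2 fold change 2.32 to 3.31, adjusted p from 3.2e-07 to 0.766). Its call was lost with voom weights, under the block and without aged libraries 1, 3 and 4, and on leaving out aged library 1 or 4 or young library 1, 2, 3, 4, 5 or 7.

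With the replicate number as a block the count was 1 gene, Ccl8 (adjusted p of Ttr 0.683), and 2 lists, neuron and choroid plexus markers, both higher. Deviations of equally numbered libraries correlated at 0.01, −0.01, −0.03, −0.02 and 0.10, so the numbers were not taken to pair the libraries.

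Of the lists 2 were called with camera, 0 with an estimated correlation, 1 on leaving Ttr out of the choroid list, 4 with the length offset (choroid plexus, immediate-early, oxidative phosphorylation and ribosomal genes, all higher), 1 without aged libraries 1, 3 and 4 (choroid plexus) and 1 to 2 on leaving out 1 library. For marker levels, 2 lists differed by the mean and 0 by the median over the list. The difference in detected genes, aged minus young, was 66.3 for counts above 0 and −549.9 for at least 5 counts, and neither passed.

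Of 2329 log2 fold changes of the 82 genes set by the naming rule under alternatives, 2236 kept their side of the threshold and direction, 53 passed only there, 11 (all Ttr) no longer passed and 29 had the other sign, none of these past the threshold. These were Lyve1 (−0.10 with a surrogate variable, −0.52 without aged libraries 1, 3 and 4), Pf4 (0.012 with the length offset), H2-Ab1 (0.31 with the offset, 0.10 without aged libraries 1, 3 and 4) and Cd74 (0.035 with voom weights, 0.012 with detected genes, 0.49 with the offset, 0.14 without aged libraries 1, 3 and 4). Slc2a1 was at 0.37 with voom weights, 0.53 with detected genes, 2.57 with a surrogate variable, 0.34 with the offset and 0.75 without aged libraries 1, 3 and 4. Without those 3 libraries Itga4 was at 0.027, Cxcr2 at −0.12, Tbk1 at −0.098 and Cox7c at −0.15. Hba-a1 was at 0.76 with DESeq2 and Psmb8 at 0.11 with the offset. On leaving out 1 library the log2 fold change of 32 of the 82 genes moved by over 1.5 times. Cd74 ranged from −0.30 to 0.094, H2-Ab1 from −0.56 to 0.023, Slc2a1 from −1.95 to 0.17, Ogn from −1.57 to 1.82 and Hba-a1 from −2.41 to 0.85. Low levels limited what could be called in the simulation: among simulated 4-fold increases the test found 72% for genes of at least 50 CPM and 0% below. The simulation called 63 genes and the main fit 1, so the adjusted threshold was easier to pass in the simulation. The 72% is therefore not the recovery in the real comparison, where Sephs2, 4.11-fold higher in aged libraries, was not called.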

Other observations

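The genes in the next 2 paragraphs and the tests of explanations were chosen after the result was seen; only the tests against other splits of the libraries were planned. The edgeR fit with legacy=FALSE called 38 genes. Among them Ccl8 had an adjusted p of 4.2e-05, and Cxcl13, a chemokine that attracts B cells, was at 103 ± 159 normalised CPM in aged and 2.05 ± 5.43 in young libraries (adjusted p = 0.00209; 0.604 with DESeq2). Enpp2, which encodes the lysophospholipase autotaxin, was at 117 ± 71.5 against 10.2 ± 10.6 normalised CPM, and DESeq2 called it too (adjusted p = 0.016). Map3k19, a kinase gene, was at 53.4 ± 26.2 against 7.65 ± 2.99. Enpp2 and Map3k19 were not on the choroid plexus marker list. They were left out, with Ttr and Kcnj13, from the other choroid plexus genes tested below. Whether their RNA came from choroid plexus was not tested. The lectin receptor gene Cd209d was at 146 ± 71.4 against 26.4 ± 26.9 normalised CPM (adjusted p = 0.0143, and 0.0484 with DESeq2), and Ms4a4c was called as well (adjusted p = 0.0203).

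A second set was called by legacy=FALSE, by DESeq2 and without aged library 2, and its 26 genes are the overlap of those fits. They include Notch2, a receptor of cell-cell signalling, at 3044 ± 1820 against 1147 ± 296 normalised CPM, the transcription factor Fli1 at 820.4 ± 506 against 271 ± 60.3, the kinase Rock1 at 424 ± 239 against 142 ± 33.5, Insig1, Skil, Clasp2 and Sephs2. Aged libraries 1, 3 and 4, which stood apart on the first principal component, weighed heavily in this set. Without them the median log2 fold change of the 26 genes was 0.49 in place of 1.45, all 26 stayed positive, and 20 lay below 0.5 times their value with all libraries. That of Notch2 was 0.36, of Fli1 0.34, of Rock1 0.71 and of Insig1 0.60, whereas Ttr and Ccl8, which belong to the set, were at 2.56 and 2.11. The 26 genes were picked by fits on these same libraries, so neither the smaller changes nor the constant sign is independent evidence. Snx24, at 9.81 ± 7.37 against 66.3 ± 9.73 normalised CPM, and Ndufv1 were the 2 genes called lower by legacy=FALSE.

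In 100 of the possible splits of the 12 libraries into 5 and 7, drawn with a fixed seed and with the real one included, 2 gave at least as many genes as the real split (1 gene, highest other 1). The drawn splits speak against chance at 0.05 for that count but do not exclude it. The count is of 1 gene, not all splits were drawn, and the call depends on single libraries. At least as many lists were called in 29 of the 100 splits (2 real, highest other 5), so chance cannot be excluded for the list calls.

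Choroid plexus transcripts were higher in aged libraries. A lower share of macrophage RNA in these libraries, made up evenly by all other brain cell types, would raise the markers of each. The mean of the astrocyte, neuron, oligodendrocyte, endothelial, mural and fibroblast levels differed by 0.08 (aged minus young, exact permutation p = 0.561). Within it the astrocyte and neuron levels were higher and the oligodendrocyte level lower in aged libraries, and endothelial and mural levels lay near the floor. The choroid level minus that mean was 1.31 ± 0.76 in aged and 0.14 ± 0.22 in young libraries (exact permutation p = 0.00253, and p = 0.0101 against the astrocyte, neuron and oligodendrocyte lists alone). The choroid level was already known to separate the groups, so these p-values add little. The values argue only against an even rise of all types, and a share made up unevenly stays open. This comparison replaced an earlier test whose result had been seen, the fry test of the oligodendrocyte list (lower in aged libraries, adjusted p = 6.0e-04). That test also went against an even rise, but its 4 genes include Mobp, and it was not run without Mobp. Choroid plexus RNA carried into the aged libraries may be a candidate explanation, and the labels name no sort: 20 other choroid plexus genes, of which 15 were higher and 5 were also on the marker list, had a mean log2(CPM + 1) of 0.78 ± 0.44 against 0.35 ± 0.11 (exact permutation p = 0.0227), but the difference of 0.43 was 0.25 without aged library 2, 0.45 without aged library 4 and 0.41 without aged library 5 (exact permutation p = 0.0545 for each). Of the 20 genes, 9 lay under 1 CPM in both groups and 5 reached 5 counts in only 1 aged library and no young one. Clic6, Folr1, Kl, Prlr and Otx2 were also on the marker list, whose level was already known to separate the groups. The p-values of the 20 genes are therefore not independent of that result, and the set was not tested without the shared genes. Clic6 was at 9.31 ± 11.5 against 0.0575 ± 0.137 CPM, Folr1 had 450 counts in aged library 2 and 0 elsewhere, and expression of Ttr by the macrophages themselves with age was not tested and stays open.

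Aged libraries 1, 3 and 4 lay at −145.0, −129 and −146 on the first principal component (15.5% of the variance), while the others lay between −24.8 and 93.3. Libraries with like numbers of genes argue against fewer captured genes as the whole cause. Aged libraries 1, 3 and 4 had 8028 to 8244 genes with at least 5 counts and 10363 to 10784 above 0. Young library 1, with 8059 and 10379, lay at −24.8, and young library 2, with 8373 and 10291, at −8.63. Over the other 9 libraries the component followed the number with at least 5 counts (Pearson r = 0.954, exact permutation p = 5.5e-05; Spearman rho = 0.933, exact permutation p = 7.5e-04) and, less closely, the number above 0 (Pearson r = 0.747, exact permutation p = 0.0203). The lines over these 9 put the 3 libraries between −17.5 and −6.27 by the first number and between 18.1 and 47.3 by the second. All 3 lay below the 95% prediction intervals, whose lowest limits were −55.2 and −58.7. They had been chosen for their place on this component, so the 95% level does not hold for them. The test by intervals replaced an earlier one, the correlation with the number of genes with at least 5 counts. The result of that earlier test had been seen and had spoken for fewer genes. A part played by the number of genes stays open, and a biological difference among aged mice was not tested. The 3 libraries were not alike on every component. On the third (11.6% of the variance) aged library 1 lay at 181, aged library 3 at −65.7 and aged library 4 at −156.

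Longer transcripts tended to higher values in aged libraries. Across 2661 genes of at least 50 CPM, which are not independent replicates, log2 fold change and log2 transcript length correlated with Pearson r = 0.243 and Spearman rho = 0.28. The median log2 fold change was 0.00 for transcripts up to 1023 bases and 0.35 for those above 3899 bases. Spread between single libraries could account for it: the slope per doubling of length was 0.07 ± 0.15 in aged and −0.05 ± 0.16 in young libraries (exact permutation p = 0.215), with young library 4 at 0.25 and aged library 2 at −0.11. A difference in RNA quality or in the cells with age stays open, and the lysosome list was not called once the trend was removed (adjusted p = 0.281).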
